A study of Mus musculus with 9 samples.

How the data were processed

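RNA from 66cl4 cells was extracted with a column kit and made into libraries with an mRNA-seq kit, and cells were kept under puromycin after hairpin transduction and selected on mCherry for the empty vector or IKK2-SE, per the labels' protocols. The deposited table holds raw counts, one whole number per gene symbol and library, with no normalization. Reads were processed with FastQC, MultiQC and STAR on the mm10 build, per the submitters' processing notes, which give no versions. The read counter, gene annotation and strand setting are not given in the sources used here, so reads from overlapping or antisense genes and from near-identical copies may not be told apart. Each column was matched to a library by its name. The columns of the 6 libraries with the Eya3 hairpin carry the number KD3 where the sample titles say KD2, and the columns were matched on the arm and replicate number. Which hairpin was used is therefore not stated here.

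The table had 52208 genes and 9 libraries, and 29899 genes had a count above 0. Library totals ran from 63601403 to 81534534. Counts of the replicates within each group differed by more than sampling noise, with a chi-square per degree of freedom from 3.62 to 18.77, so no library was taken as a repeat of another. Genes with enough counts for a test were kept with edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 16766. Positions are 1-based on GRCm38/mm10 from the GENCODE annotation, and 96.9% of the tested genes had one.

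Counts were scaled with TMM and tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood fits with robust spread over all 9 libraries, with group as the only term and 6 residual degrees of freedom. The common biological coefficient of variation was 5.26%. P-values were adjusted by the Benjamini-Hochberg method over the tested genes and a gene was called at 0.05. The standard error of a log2 fold change was its size divided by the square root of F. CPM are TMM-scaled. Where a group had no counts, the fold is a lower bound against 3 counts over the group, which covers counting error only. The 3 comparisons were knockdown against scramble, add-back against knockdown and add-back against scramble, with an F test over the 3 groups.

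The gene lists, the rule for the genes named in the report, the tests of the 3 comparisons and all alternatives but 1 were fixed before the data were examined. Tests, genes and alternatives chosen later are stated as such where they are given. The 23 lists included NF-kB targets, NF-kB pathway components, chemokines and growth factors, interferon-stimulated genes, MHC class I pathway, natural killer ligands and checkpoints, cell cycle, p53 and DNA damage, Myc targets, mesenchymal genes, epithelial genes, matrix and proteases, TGF-beta and YAP targets, hypoxia and glycolysis, unfolded protein and stress, cholesterol synthesis, oxidative phosphorylation, macrophage, lymphocyte, endothelial and fibroblast markers, and genes that track RNA quality. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over all 69 tests, and again with an estimated correlation. Named genes were 9 fixed genes, the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 1, libraries that did not overlap and a proper symbol (5 each way for add-back against scramble), the 10 opposed genes with the largest knockdown change, and up to 4 members of each list with the smallest adjusted p. With 3 libraries against 3, chance alone gives no overlap in 10% of unchanged genes.

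The procedure was tested on simulated counts, repeated 5 times on about 16085 genes, with 200 drawn genes changed by the 4 folds below and the other NF-kB targets lowered by 0.5 on the log2 scale in the knockdown arm alone. The recovered shares are of the drawn genes. For knockdown against scramble, 69.6% of genes changed 1.25-fold were recovered, 88.8% at 1.5-fold, 96.8% at 2-fold and 100% at 4-fold. The share of calls that fell on unchanged genes was 7.35%, 5.49% and 8.46% in the 3 comparisons. Single repeats ranged up to 13.27% in add-back against scramble, so the true share can exceed the nominal 5%. Far fewer genes were changed in the simulation than were called against scramble in the data (57.5% for knockdown and 55.8% for add-back). The simulated shares, recovered or false, therefore do not carry over to those 2 comparisons. The repeats were raised from 1 to 5 after the first had given the 13.27%, and after trended dispersion and fits without robust spread had been tried on simulated counts and not kept. Of 144.4 genes set to be opposed, 118.2 were found on average. At the preset correlation, camera called 2.4 and 2 lists on average in the first 2 comparisons, where 1 list was moved. It called 0.4 in add-back against scramble, where no list was moved. The moved list shares 12 tested genes with the chemokine list.

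The labels give each group replicates 1 to 3, and whether equal numbers mark paired cultures was checked from the deviations of each library from its group mean. Over all 16766 genes no comparison met the rule that every pair correlates above 0.1 (lowest 0.004 for add-back against knockdown). Over the 9251 genes with a mean log2 CPM above 3, the 3 pairs of add-back and knockdown libraries did, with correlations from 0.147 to 0.612, and the other comparisons did not. However, add-back replicate 3 and knockdown replicate 2, with unequal numbers, correlated at 0.178, above the 0.147 of the 2 libraries numbered 2. The well-expressed genes were looked at first and all genes second, both before any blocked fit was run but after the unblocked calls had been seen. The expression limit was not planned, and no label states that numbers mark a shared day, so the pairing is unsettled. The blocked values are therefore given beside the counts, list calls and single genes of the report whose call they change or whose count they move by over 1.5 times.

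Alternatives were RLE size factors, library totals, no low-count filter, CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma voom, no robust spread, only the 2 groups compared, the replicate block, stricter thresholds and leaving out each library in turn.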

Results

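Gene expression was measured in 66cl4, a mouse mammary carcinoma line used as a model of triple-negative breast cancer, by sequencing of messenger RNA in 9 libraries. The 3 groups had 3 biological replicates each. Scramble control cells carried a non-targeting short hairpin RNA and an empty vector. Knockdown cells carried a hairpin against Eya3, which encodes a transcriptional coactivator and phosphatase of the Eyes absent family, and the empty vector. Add-back cells carried the Eya3 hairpin and IKK2-SE, a constitutively active form of the kinase that switches on NF-kB signalling. The scramble libraries held 63601403, 77149018 and 73960228 counts, the knockdown libraries 81534534, 79940304 and 76469567, and the add-back libraries 75538142, 71323395 and 69381510. Of 52208 genes in the table, 29899 had a count and 16766 were tested. On the first principal component, which held 74.3% of the variance, the scramble libraries lay apart from both knockdown arms. The second, with 8.8%, parted the knockdown from the add-back libraries. Levels are given as library-scaled counts (CPM) as mean ± SD with n = 3, and fold changes on the log2 scale as estimate ± SE from edgeR's quasi-likelihood test. The labels do not say whether the replicates came from separate transductions, so p-values measure the spread between these cultures.

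The targeted gene was examined first. Eya3 (chromosome 4, 132638987 to 132724765, plus strand, GRCm38/mm10, protein coding) stood at 62.7 ± 1.60 CPM in the scramble cells, 25.0 ± 0.60 CPM in the knockdown cells and 26.6 ± 2.23 CPM in the add-back cells. The single libraries gave 62.96, 64.13 and 60.91 CPM with the scramble hairpin, 25.34, 25.29 and 24.28 CPM with the Eya3 hairpin, and 28.99, 26.05 and 24.66 CPM with the hairpin and IKK2-SE. Every scramble library lay above every knockdown and add-back library. Eya3 fell by 1.33 ± 0.06 in the knockdown cells (edgeR adjusted p = 5.97e-12) and by 1.24 ± 0.06 in the add-back cells (edgeR adjusted p = 1.52e-11), both against scramble. Between the add-back and knockdown cells it differed by 0.09 ± 0.06 (edgeR adjusted p = 0.406). Ikbkb (chromosome 8, 22659212 to 22706589, minus strand), the mouse gene for IKK2, was at 47.8 ± 2.56 CPM, 44.3 ± 0.43 CPM and 48.6 ± 1.27 CPM in the scramble, knockdown and add-back cells. Its difference between add-back and knockdown cells was 0.13 ± 0.05, which did not pass the threshold (edgeR adjusted p = 0.081). It passed with the replicate number as a block (0.0243), with library totals as the scaling (0.0362) and without scramble replicate 3 (0.0489), and adjusted p ran from 0.0243 to 0.197 over the alternatives for Ikbkb. Between knockdown and scramble cells Ikbkb differed by -0.11 (edgeR adjusted p = 0.0532), which passed with the block (0.0227), library totals (0.00852), the CPM filter (0.0441) and without scramble replicate 2 (0.0487), and ran up to 0.284.

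**Figure D1:**
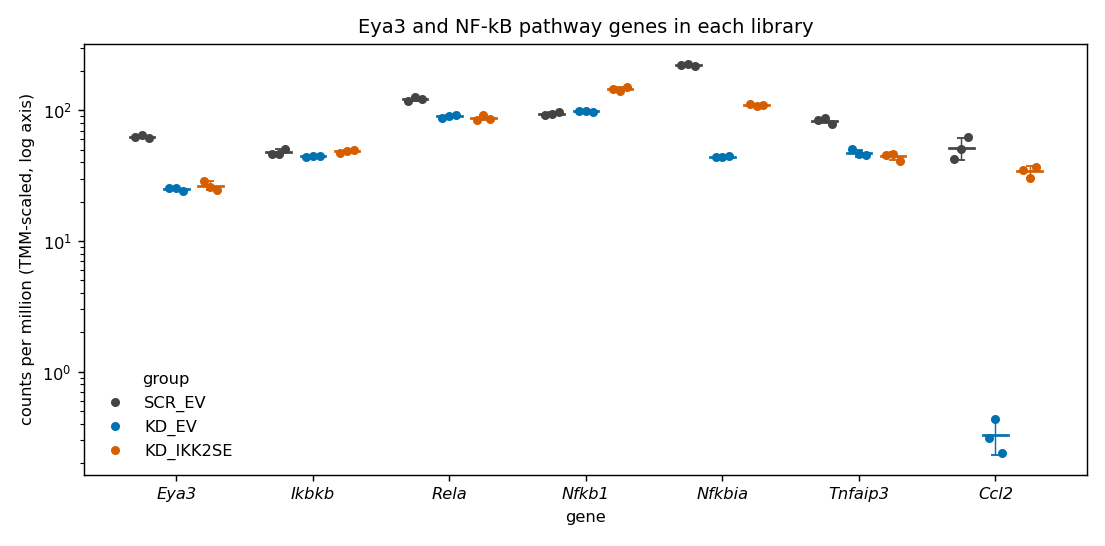
CPM (log axis) of 7 genes in each library, with a point per library, a bar at the mean of 3 libraries and error bars of 1 SD, coloured by group. Eya3 was lower in both knockdown arms, and Ccl2 was at 0.328 CPM in the knockdown cells against 51.6 CPM in the scramble and 34.0 CPM in the add-back cells.

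The knockdown and scramble cells were compared to ask which transcripts differ when Eya3 is reduced. Ccl2 (chromosome 11, 82035571 to 82037453, plus strand), a chemokine that attracts monocytes, fell by 7.29 ± 0.23, from 51.6 ± 9.95 CPM to 0.328 ± 0.10 CPM (edgeR adjusted p = 6.12e-10). Nfkbia (chromosome 12, 55489410 to 55492647, minus strand), the NF-kB inhibitor that is itself induced by NF-kB, fell by 2.32 ± 0.04 (edgeR adjusted p = 3.04e-17). Tnfaip3 (chromosome 10, 19000910 to 19015657, minus strand), a deubiquitinase that restrains the pathway, fell by 0.82 ± 0.06. Rela (chromosome 19, 5637483 to 5648130, plus strand), the p65 subunit, fell by 0.43 ± 0.04. Nfkb1 (chromosome 3, 135584655 to 135691547, minus strand) differed by 0.06 ± 0.04 (edgeR adjusted p = 0.16). It lies in a block of 41 neighbouring genes with a median change of 0.52, while the block that holds Rela had -0.06. Nfkb1 and Rela therefore cannot be set against each other without regard to this shift. The block that holds Tnfaip3 was shifted as well, with a median of 0.32, opposite to the fall of Tnfaip3. Myc (chromosome 15, 61985391 to 61990374, plus strand) rose by 0.52 ± 0.04. Cd274 (chromosome 19, 29367455 to 29388095, plus strand), which encodes the checkpoint ligand PD-L1, differed by 0.10 ± 0.10 (edgeR adjusted p = 0.43).

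Of 45 measured NF-kB target genes, 31 fell, 3 rose and 11 did not pass the test, with the same 31 and 3 when adjusted over the list alone. Traf1, a signalling adaptor, fell by 3.94 ± 0.09 and the neutrophil-attracting chemokines Cxcl5 and Cxcl1 fell by 3.09 ± 0.08 and 2.27 ± 0.06. The list's median was -0.63 (camera on the edgeR fit, adjusted p = 4.77e-13), with adjusted p = 0.149 with an estimated correlation. Of 27 measured chemokines and growth factors, 15 fell and 2 rose, and the counts were the same when adjusted over the list alone (camera adjusted p = 1.61e-07, and adjusted p = 0.0898 with an estimated correlation). Cxcl3 fell by 2.76 ± 0.07 and Cxcl12 by 1.18 ± 0.04. The NF-kB target and chemokine lists share 12 tested genes, so they are not separate evidence.

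Genes of antigen presentation and of immune recognition were tested as lists. Of 18 measured genes of the MHC class I pathway, 10 fell and 3 rose, the same when adjusted over the list alone (camera adjusted p = 0.0411, and adjusted p = 0.469 with an estimated correlation). This call was also lost with the CPM filter (0.0844) and limma voom (0.0784), 3 of 18 alternatives in all. Psmb8, an immunoproteasome subunit, was at 19.2 ± 0.24 CPM in the scramble and 0.0763 ± 0.050 CPM in the knockdown cells, and Tapbp, the tapasin chaperone, fell by 0.87 ± 0.04. Of 19 measured ligands and checkpoints seen by natural killer cells, 10 fell and 2 rose, the same when adjusted over the list alone (camera adjusted p = 0.0433, and adjusted p = 0.379 with an estimated correlation). This call was also lost with the CPM filter (0.0575), limma voom (0.0536) and without scramble replicate 3 (0.0605), 4 of 18 in all. Pvr, a ligand of the receptors CD226 and TIGIT, fell by 0.96 ± 0.06, and Cd48 fell by 3.98 ± 0.18. Of 6 measured macrophage markers, 3 fell and none rose, the same when adjusted over the list alone (camera adjusted p = 0.0467, and adjusted p = 0.289 with an estimated correlation). The macrophage list lost its call in 11 of 18 alternatives, among them the replicate block (0.106) and 6 that each left out 1 library: scramble replicate 1 (0.069) or 3 (0.0654), knockdown replicate 1 (0.0531) or 2 (0.0555), and add-back replicate 1 (0.0586) or 3 (0.0746). The fallen markers were Cd14, Cd68 and Mrc1, at 15.3, 14.5 and 6.0 CPM in the scramble cells and 7.5, 4.2 and 0.929 CPM in the knockdown cells.

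The other lists did not pass the camera test in this comparison, although many members moved singly. Rises and falls numbered 7 and 17 among 30 NF-kB pathway components, 7 and 19 among 40 interferon-stimulated genes, 9 and 20 among 40 cell cycle genes, 11 and 10 among 26 p53 and DNA damage genes, and 6 and 21 among 40 Myc targets. They numbered 5 and 8 among 20 mesenchymal genes, 5 and 7 among 13 epithelial genes, 13 and 11 among 29 matrix and protease genes, and 10 and 10 among 25 TGF-beta and YAP targets. They numbered 13 and 3 among 27 hypoxia and glycolysis genes, 14 and 7 among 28 unfolded protein and stress genes, 11 and 7 among 24 cholesterol synthesis genes, and 16 and 3 among 30 oxidative phosphorylation genes. For cells of other types they numbered 0 and 1 among 3 lymphocyte markers, 1 and 5 among 8 endothelial markers, and 4 and 5 among 9 fibroblast markers. Among 17 genes that track RNA quality 1 rose and 1 fell. Of those not called, mt-Atp6 and mt-Co3 passed as lower with the replicate number as a block (adjusted p = 0.0463 and 0.0392) and with DESeq2 (0.0482 and 0.0442). Over the alternatives their adjusted p ran up to 0.231 and 0.274.

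Among the largest changes were transcripts present in one arm and near absent in the other. Nkd1, an antagonist of Wnt signalling, had no counts in the knockdown libraries against 35.7 ± 0.89 CPM in the scramble cells, at least 2790-fold lower against a floor of 3 counts over the group. Gypc, Tmtc2 and Ckb were at least 831, 719 and 544-fold lower in the same way, and Procr, the endothelial protein C receptor, went from 114 CPM to 0.0168 CPM. In the other direction Col3a1, a fibrillar collagen, was at 13.4 ± 0.50 CPM in the knockdown and at no counts in the scramble cells, at least 976-fold higher. Trp63, a basal epithelial transcription factor, rose from 0.0274 CPM to 18.8 CPM. Thbs1, which encodes thrombospondin, was expressed in both arms and rose from 29.7 CPM to 1123 CPM. Serpina1c and Serpina1a also rose, but they belong to a family of near-identical genes and reads may be split between copies. Altogether 37 genes had no counts in one arm and at least 1 CPM in the other, 32 of them without counts in the knockdown cells.

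In all, 9643 of 16766 genes (57.5%) changed between knockdown and scramble cells at a Benjamini-Hochberg adjusted p below 0.05, with 4636 higher and 5007 lower. At least 2-fold changes numbered 2458, with 889 higher. The comparison rests on 1 Eya3 hairpin and 1 scramble control, and separate transductions of each are not stated. Differences between the cells that do not come from Eya3 are therefore included in these counts. Blocks of neighbouring genes also shifted together between the lines. The median log2 change was -0.36 over 789 tested genes of chromosome 10, 0.25 over 869 of chromosome 3 and 0.31 over 767 of chromosome 17, against 0.01, 0.00 and -0.04 between add-back and knockdown cells. Of 384 blocks of 41 neighbouring genes, 54 had a median at least 0.3 from 0, against at most 4 in 1000 shuffled gene orders.

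**Figure D2:**
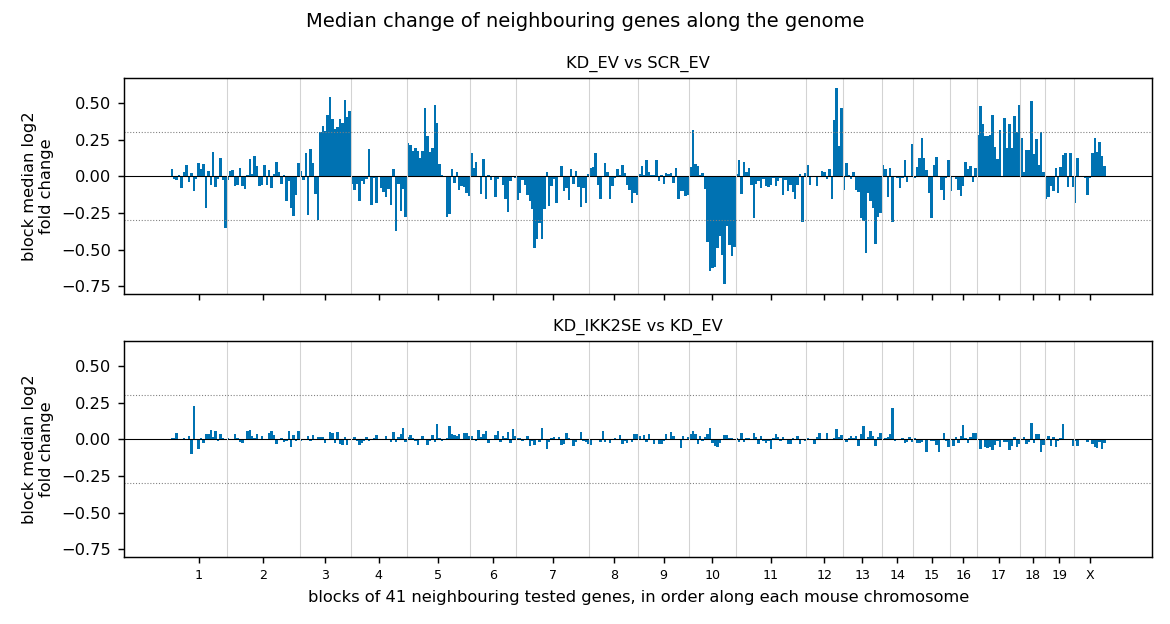
Median log2 fold change of blocks of 41 neighbouring tested genes along the mouse chromosomes, for knockdown against scramble cells (upper) and add-back against knockdown cells (lower), with dotted lines at 0.3 either side of 0. Long stretches of chromosomes 3, 10 and 17 lie away from 0 in the upper panel, and no block passes 0.3 in the lower panel.

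The add-back and knockdown cells were compared to ask which transcripts differ with active IKK2 when Eya3 is low. Differences between these separately selected cells that do not come from IKK2-SE are included. No group had the scramble hairpin with IKK2-SE, so a general effect of IKK2-SE cannot be told from a return of Eya3-dependent changes. Ccl2 rose by 6.68 ± 0.23, to 34.0 ± 3.48 CPM (edgeR adjusted p = 2.69e-08), and Ccl7, a related monocyte chemokine, rose by 8.69 ± 0.38. Ccl7 had only 1, 3 and 0 counts in the knockdown libraries, so the size of its fold rests on few reads. Lcn2, the iron-binding lipocalin, rose from 3.22 ± 0.71 CPM to 273 ± 32.0 CPM (edgeR adjusted p = 3.55e-10). The cytokine Il1a and the acute-phase gene Saa3 rose by 7.22 ± 0.33 and 6.23 ± 0.19, and the protease inhibitor Slpi by 4.04 ± 0.13. Il1a was also near the floor, with 4, 2 and 7 counts in the knockdown libraries. Nfkbia rose by 1.31 ± 0.04 and Nfkb1 by 0.56 ± 0.04, while Tnfaip3 and Rela differed by -0.09 ± 0.06 and -0.04 ± 0.04 and did not pass the test (edgeR adjusted p = 0.44 and 0.61). Myc was at 306.2, 332.1 and 300.1 CPM in the add-back libraries, against 348, 368 and 357.3 CPM in the knockdown libraries.

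Of 45 measured NF-kB targets, 31 rose and 2 fell, or 32 and 3 when adjusted over the list alone, with a median of 0.93 (camera adjusted p = 2.19e-150, and adjusted p = 0.000713 with an estimated correlation). Of 27 chemokines and growth factors, 17 rose and 2 fell, or 20 and 2 when adjusted over the list alone (camera adjusted p = 1.54e-99, and adjusted p = 0.00037 with an estimated correlation). Cxcl3, Cxcl5 and Cxcl1 rose by 3.69 ± 0.07, 3.68 ± 0.08 and 3.31 ± 0.07. These were the only 2 of the 69 list tests that passed with an estimated correlation. With the preset correlation 15 passed, a count that 30 of 100 splits of the 9 libraries into groups of 3, the real one included, reached.

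Of 40 interferon-stimulated genes, 31 rose and 1 fell, or 34 and 1 when adjusted over the list alone, led by Zbp1 at 1.66 ± 0.16 and Gbp2 at 1.28 ± 0.08 (camera adjusted p = 3.91e-22, and adjusted p = 0.372 with an estimated correlation). Of 18 MHC class I pathway genes, 9 rose and none fell, also when adjusted over the list alone (camera adjusted p = 0.000232, and adjusted p = 0.241 with an estimated correlation). The peptide transporter gene Tap2 rose by 0.55 ± 0.06 and Tapbp by 0.44 ± 0.04. Of 30 NF-kB pathway components, 10 rose and 1 fell, or 13 and 1 when adjusted over the list alone, with Tlr2 at 1.05 ± 0.10 (camera adjusted p = 0.000622, and adjusted p = 0.135 with an estimated correlation). Of 19 natural killer ligands and checkpoints, 3 rose and 1 fell, or 6 and 1 when adjusted over the list alone (camera adjusted p = 0.00301, and adjusted p = 0.197 with an estimated correlation). The 3 were Icam1, Clec2d and Fas, of which Icam1 and Fas are also on the NF-kB target list. Of 6 macrophage markers, 3 rose and none fell, or 3 and 1 when adjusted over the list alone (camera adjusted p = 0.000256, and adjusted p = 0.0898 with an estimated correlation).

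Of 27 hypoxia and glycolysis genes, 14 fell and none rose, or 20 and none when adjusted over the list alone, among them Ndrg1 with a fall by 0.62 ± 0.10 and the angiogenic factor Vegfa with a fall by 0.42 ± 0.05 (camera adjusted p = 2.56e-09, and adjusted p = 0.551 with an estimated correlation). Of 28 unfolded protein and stress genes, 13 fell and 2 rose, or 14 and 5 when adjusted over the list alone (camera adjusted p = 0.0403, and adjusted p = 0.445 with an estimated correlation). This call was lost in 7 of 18 alternatives, also with library totals (0.0784), the CPM filter (0.0835), only the 2 groups fitted (0.0563), and without knockdown replicate 1 (0.057) or add-back replicate 1 (0.0566) or 3 (0.0579). Of 20 mesenchymal genes, 7 fell and 2 rose, or 8 and 2 when adjusted over the list alone, with Vim falling by 0.50 ± 0.06 (camera adjusted p = 0.0467, and adjusted p = 0.289 with an estimated correlation). The mesenchymal call was lost in 8 of 18 alternatives, also with the replicate number as a block (0.0607), library totals (0.0572), only the 2 groups fitted (0.0712), and without scramble replicate 2 (0.0533), knockdown replicate 3 (0.0982) or add-back replicate 1 (0.0908) or 3 (0.0549). Of 29 matrix and protease genes, 6 rose and 8 fell, or 8 and 10 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.91). Among its members Col1a2 fell by 1.33 ± 0.14, and Mmp3 and Mmp10 rose by 3.77 ± 0.30 and 1.64 ± 0.10. None of 30 oxidative phosphorylation genes passed edgeR's test, but Uqcrq, at -0.11 (adjusted p = 0.0851), passed with the replicate number as a block (0.0187) and without add-back replicate 1 (0.0464), and its adjusted p ran up to 0.246 over the alternatives.

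In all, 1749 genes (10.4%) changed, 941 higher and 808 lower, and 279 changed at least 2-fold, 230 of them higher. With library totals as the scaling, 65.9% of the changed genes were higher, against 53.8% in the main result. With the replicate number as a block, 2678 genes changed.

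**Figure D3:**
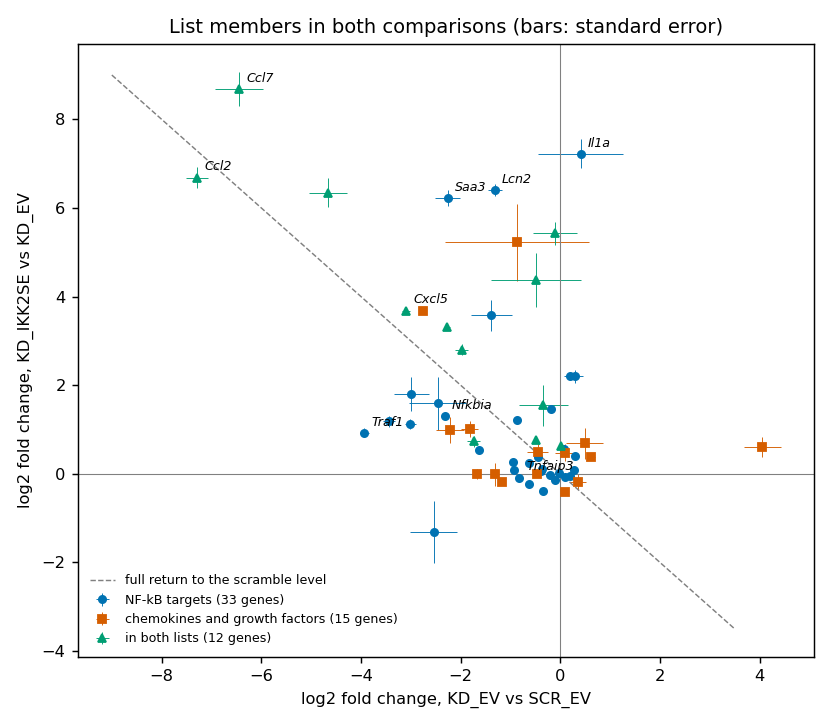
Log2 fold change of knockdown against scramble cells (horizontal) and of add-back against knockdown cells (vertical) for the measured NF-kB targets and chemokines and growth factors, with standard errors as bars; on the dashed line a gene would be back at the scramble level. Ccl2 lies near the line, Lcn2 and Saa3 lie above it, and Traf1 lies below it.

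Add-back cells were set against scramble cells to ask how near their levels came to the scramble level. Ccl2 remained 0.60 ± 0.13 below the scramble level (edgeR adjusted p = 0.00238) and Nfkbia 1.01 ± 0.03 below it (edgeR adjusted p = 4.98e-13). Cxcl1 and Saa3 were above the scramble level by 1.04 ± 0.06 and 3.96 ± 0.15, and Ccl20, a chemokine that attracts lymphocytes and dendritic cells, by 5.33 ± 0.26. The fold of Ccl20 rests on 11, 3 and 16 counts in the scramble libraries. Tnfaip3 and Traf1 stayed 0.91 ± 0.06 and 3.01 ± 0.09 lower than in scramble cells. Cd274 passed edgeR's test as higher than in scramble cells. Its adjusted p ran up to 0.175 over the alternatives, without add-back replicate 1, so that call is not firm. Nkd1, Ckb, Tmtc2 and Psmb8 remained near absent in the add-back cells, and Col3a1, Trp63 and Spint2 remained high, with Col3a1 at 12.0 CPM and Trp63 at 26.3 CPM. Altogether 9352 genes differed between add-back and scramble cells, 4533 higher and 4819 lower, with 2351 at least 2-fold. No list passed the camera test here. Over the 3 groups together, 10075 genes changed by edgeR's F test.

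A gene was counted as opposed when it changed in the knockdown cells and changed the other way with IKK2-SE. There were 1043 such genes, 546 lower and then higher and 497 higher and then lower. They made up 10.8% of the 9643 genes that differed between knockdown and scramble cells, whatever the cause of the difference. Lists of the same sizes drawn independently would share 504.4, and 359 genes moved the same way in both comparisons against 501.5 for independent lists. Of the 1043, 308 did not differ from scramble in the add-back cells, 669 were still short of the scramble level and 66 were beyond it. Among the NF-kB targets, 22 of the 34 that differed between knockdown and scramble cells were opposed. Of the 22, 11 were beyond the scramble level, 10 short of it and 1 not different from it. Among chemokines and growth factors 11 of 17 were opposed, and among interferon-stimulated genes 15 of 26. Beside Ccl2 and Ccl7, the opposed genes with the largest knockdown change included Scin, Lgr6, Vegfc, Ntn1 and the zinc transporter Slc39a4, which rose from 0.59 CPM to 3.49 CPM with IKK2-SE against 46.9 CPM in scramble cells. The rise of Scin with IKK2-SE (edgeR adjusted p = 0.0126) did not pass without add-back replicate 3 (0.0701), the highest value over its alternatives, or with only the 2 groups fitted (0.0557). Hspb7, a small heat shock protein gene, was opposed in the other direction, at 0.0534, 24.8 and 6.89 CPM in the scramble, knockdown and add-back cells.

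Both comparisons use the knockdown libraries, with opposite sign, so chance values in those libraries alone make fold changes run opposite. In 20 simulations all groups were drawn from the mean of the 9 libraries, and the correlation of the fold changes across genes was -0.489. No gene was opposed there, which the setting fixed in advance, since no group differed. The observed correlation across genes was -0.246, and the covariance was -0.185 against -0.0257 in the simulations, a difference of -0.159. Genes near absent in the knockdown cells were simulated at a higher mean. Noise from the shared libraries may therefore exceed the simulated value, and the difference does not measure reversal. Part of the excess of opposed genes may come from the shared libraries, since 3 knockdown libraries cannot be split into parts of 2. The count was 694 without knockdown replicate 2, and 1617 with the replicate number as a block.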

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

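The alternatives were planned, except removal of the regional shift, which was chosen after seeing the data. With RLE size factors, library totals, either other count filter, DESeq2, limma voom, no robust spread or only the compared groups, the counts of changed genes stayed within 1.5 times the main ones, as did the opposed genes where 3 groups were fitted, and Eya3 kept its fall under all of them. The replicate block gave 2678 genes for add-back against knockdown and 1617 opposed genes, and moved no other count of genes that far. It ended the macrophage call of knockdown against scramble (camera adjusted p = 0.106) and the mesenchymal call of add-back against knockdown (0.0607). Requiring a log2 change of at least 1 left 2458, 279 and 2351 genes in the 3 comparisons and 134 opposed genes. An adjusted p below 0.01 left 961 for add-back against knockdown and 541 opposed, because a stricter threshold calls fewer genes.

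Without single libraries the opposed count ran from 694 (without knockdown replicate 2) to 1023, and knockdown against scramble from 8799 to 9898, add-back against knockdown from 1168 to 1800, add-back against scramble from 8500 to 9511, the F test from 9069 to 10093, the list tests from 12 to 15 and Eya3 from -1.35 to -1.30. List calls numbered 24 with no count filter, for which the cause was not tested, and 2 with an estimated correlation, which allows for genes that move together. NF-kB targets and chemokines in add-back against knockdown cells kept their call in all 18 alternatives.

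Of 5987 values of 334 named gene results, 5872 kept direction and side of the threshold, 72 lost the call, 39 gained it and 4 changed sign. The sign changes were in genes near the floor that were called in no fit. For Cd79a, add-back against scramble, limma voom gave 0.011 against -0.06, and single libraries left out gave -0.24 to 0.37. For Il2rg, add-back against knockdown, they gave -0.31 to 1.35 against 0.55. The cause was not tested.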

Other observations

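The tests of gene order, of the region-corrected count, of other cell types, of swapped libraries, of line differences and of Ikbkb, and the split count with an estimated correlation, were chosen only after the results they bear on were seen, and so was the SE margin in the copy number test.

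The genes with no counts in the knockdown cells and at least 1 CPM with IKK2-SE were picked out after their values were seen. Haptoglobin (Hp), the stefin gene Stfa3 and the pentraxin Ptx3 had no counts in the knockdown libraries and 1.88 ± 0.49, 1.67 ± 0.22 and 1.22 ± 0.26 CPM in the add-back cells, at least 147, 131 and 95-fold higher. The inducible nitric oxide synthase Nos2 rose from 6.21 CPM to 43.6 CPM (edgeR adjusted p = 0.000107), also chosen after its value was seen. Ltbp2, which encodes a matrix protein, rose by 1.86 ± 0.06 to 77.2 CPM, after a knockdown fall by 1.76 ± 0.06 from 71.7 CPM.

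Between knockdown and scramble cells, long runs of neighbouring genes moved together, such as 338 genes at 71254980 to 115270377 of chromosome 10 (GRCm38/mm10) with a median of -0.59, and add-back cells showed -0.57 over the same genes. Chance order of genes was argued against, since 54 blocks lay at least 0.3 from 0 and none of 1000 shuffled orders reached that, and so was a GC or length trend, since 53 blocks remained after it was removed. Unequal chromosome copy number in the lines may account for the runs and stays open: it needs genes of high and low expression to shift alike, within 0.15, and on chromosome 17 they differed by 0.15 ± 0.04 (bootstrap SE), while on chromosome 10 they differed by 0.02 ± 0.08. Chromosome 3, whose median of 0.246 was just under the limit of 0.25 set for this test, differed by 0.21 ± 0.06, but so did chromosomes with little shift (chromosome 15, median 0.027, by 0.21 ± 0.06, and X, median 0.067, by 0.21 ± 0.06), so a gap of this size is not specific to shifted chromosomes and the test does not settle the matter. Counts of RNA cannot separate copy number from regional regulation.

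The second pattern was the breadth of the knockdown difference, with 9643 genes, and of those changed at least 2-fold 13.8% lay in regions shifted the same way, against 14.1% of calls under 2-fold and 10.7% of all placed genes. The share met neither limit written beforehand (over 50% if segments gained or lost were the cause, under 10% if not), and the lower limit was badly set, below the share over all genes, so segments may contribute and stay open, while 90.1% stayed at least 2-fold once the regional median was subtracted (2132 of 2367), which argues against the shift of the region as the source of most of them but follows largely from the 13.8% and is not separate evidence. Leukocytes or fibroblasts mixed into one line are argued against by a highest group mean of 0.712 CPM among Ptprc, Tyrobp, C1qa, Cd3e, Pecam1, Dcn and Lum, although single markers of the fixed lists were higher in one line, with Cd14 and Cd68 at 15.3 and 14.5 CPM in the scramble cells and Col3a1 at 13.4 CPM in the knockdown cells, and 4 of 9 fibroblast markers rose while 5 fell. Eya3 was on the wrong side of the midpoint between scramble and knockdown levels in 0 libraries. This argues against a library swapped between the scramble arm and the other arms. Eya3 cannot show a swap between knockdown and add-back libraries, which carry the same hairpin. Differences between separately transduced and selected cells apart from Eya3 may contribute. With 1 hairpin and 1 scramble control they cannot be told apart from loss of Eya3. Of the 37 genes without counts in one arm, those lost in the knockdown cells had group means of at most 0.0381 CPM (Zmym6) with IKK2-SE, and a second hairpin or a rescue with Eya3 would separate the causes.

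The third pattern was the level of Ikbkb, which differed by 0.134 on the log2 scale between add-back and knockdown cells (95% interval 0.036 to 0.231). IKK2-SE made from mouse Ikbkb sequence and counted as Ikbkb in amounts that at least double it is argued against by that interval. Absence of active IKK2-SE was set against the 31 of 45 NF-kB targets that were higher. That count was already known when this check was chosen. It includes differences between the separately selected cells that do not come from IKK2-SE, so it is not a separate test of activity. IKK2-SE sequence not counted as a mouse gene, as with a construct from another species, may account for the level and stays open, since 0 genes in the table name the construct or mCherry.

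Other splits of the libraries were counted. For each pair of groups 1 of 10 splits of the 6 libraries, the real one, gave as many changed genes, with 9643, 1749 and 9352 genes against 0 in every other split, and 10 splits are too few for a share below 0.05. For the F test 1 of 100 splits of the 9 libraries, the real one, gave 10075 genes, against 8796 in the highest other split. The next highest gave 8507 and 8319, and after those the highest was 46. The count argues against a random grouping of these libraries. Since some other groupings came near it, it says little on the division into just these 3 groups. Libraries of one arm share their cells, so the splits cannot exclude chance differences between the cells of the arms. For opposed genes 1 of 100 gave 1043, against 0 in every other split, but the regrouped pairs of arms above also gave 0 changed genes, which leaves none to be opposed, so these splits do not decide on chance for the opposed genes. The 15 list calls at the preset correlation were reached by 30 of 100 splits, with up to 23 in another split, so chance cannot be excluded for that count. With an estimated correlation, 4 of 100 splits, the real one included, reached the 2 calls, with up to 4 in another split.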
